A study of Mus musculus with 23 samples.

How the data were processed

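Small RNA of mouse retinas was sequenced at postnatal day 90 in 23 libraries, 1 per retina. Per the labels' protocols, retinas were flash frozen, RNA was extracted with Trizol and libraries were made with the NEXTflex small RNA v3 kit. The groups are wild-type C57B mice and heterozygous P23H rhodopsin knock-in mice, which were left uninjected or given saline, or DNA nanoparticles carrying genomic human rhodopsin (human gRHO) or genomic mouse rhodopsin (mouse gRho).

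The authors deposited read counts per miRNA locus and annotation class (mature, precursor, stemloop and unannotated), and a table of read counts per library and class of alignment. The submitters' processing notes name DESeq2, with no version. The aligner, counting program, miRNA annotation and genome build are not given in the sources used here, so no coordinates are printed. Mature rows carry a locus name and no arm: the values below belong to the locus row as deposited, and neither the 5p nor the 3p arm can be read from it. Rows of a locus with several copies (such as mir-9-1, mir-9-2 and mir-9-3) can share reads and are uncertain as separate measurements. No column of the matrix was left unused (0 columns).

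Column totals of the precursor, stemloop and unannotated rows equalled the alignment table in 23 of 23 libraries. Those of the 903 mature rows reached between 10.4% and 19.5% of the mature miRNA reads of that table (median 13.4%). Many mature rows also jumped between 2 levels across libraries, and these were not compared as counts of 1 miRNA. A row was set aside as two-level, without regard to group, when its highest count was at least 30 and the largest gap in its sorted log2(CPM + 0.5) was at least 3.5, or at least 2 with at least 2 libraries on each side. This removed 65 of 337 rows that reached 30 reads in a library. The rule was set after the data were examined, and the design fixed before had assumed that each row counted 1 miRNA. Jumps between closer levels would go unseen.

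The titles were read as cage number, ear mark and eye. This reading is an inference, not a statement of the labels. All uninjected mice share a leading title number, as do the human gRHO mice, and no such number recurs across groups. If these numbers are cages, treatment cannot be told apart from cage, and cage mates were counted as independent. Libraries that differ only in the eye were summed to 1 mouse, which gave 15 mice: 2 WT, 3 uninjected, 1 saline, 2 human gRHO and 7 mouse gRho. WT titles have another form, and those libraries were counted as 2 mice. If the reading is wrong, p-values measure the spread between these sums only, which may be partly technical. Among the 4 mouse gRho mice with both eyes, the correlation between the eyes' deviations from the group mean (across 126 miRNA rows, which are not independent) had a median of 0.30 and ranged from -0.65 to 0.72. Its median was -0.13 over the 51 pairs of eyes from different mice. Outside saline, whose libraries were not compared in this way, no 2 libraries of a group agreed within counting noise (smallest chi-square per degree of freedom 19.1).

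Counts were tested with edgeR 4.0.16 (quasi-likelihood, robust) in R 4.3.3, all 5 groups in 1 fit, with TMM factors on the mature miRNA reads of the alignment table. The 382 rows with at least 10 counts in at least 3 mice were tested, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM were computed from the deposited counts, the mature miRNA reads and the TMM factors. Depth ranged from 6980992 to 25046363 mature miRNA reads per mouse. At 382 rows the median standard error of a log2 fold change ran from 0.44 (mouse gRho against uninjected) to 0.77 (human gRHO against saline). Saline had 1 mouse, so its comparisons assume that this mouse varies like the others. Right and left eyes were compared in 8 mice with a term for the mouse. The 17 lists of miRNAs were fixed before the data were examined and matched by locus, since arms are not named. They cover the miR-183 cluster, the miR-204 family, miR-124 with miR-9, the miR-181 family, activity-regulated miRNAs, Mueller glia, miRNAs reported up in retinal degeneration, microglia and leukocytes, endothelial and mural cells, red blood cells, muscle, surface epithelium with lens and cornea, liver, the let-7 and miR-29 families, the miR-17/92 clusters and the Dlk1-Dio3 cluster. Several lists share members. Lists were tested with camera (limma 3.58.1, preset correlation 0.01), with an estimated correlation and with fry.

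The rule for named miRNAs was also fixed before. It takes, per comparison, up to 12 higher and 12 lower rows past the threshold with a mean of at least 10 CPM, every list member past the threshold, and 10 retinal, glial and immune miRNAs as values against uninjected. Where there was no call it takes the 3 smallest p-values. Called rows under 10 CPM are named as well because their number is small, and were chosen after their values were seen. The row of mir-146a is two-level, so no fold change is given for it.

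The pipeline was tested on simulated counts with 40 changed miRNAs in each of 10 data sets per comparison, a number chosen to leave most of the 382 rows unchanged. For uninjected against WT, 7.32% of 2-fold, 54.7% of 4-fold and 78.0% of 8-fold changes were called among 382 rows. For mouse gRho against uninjected these shares were 17.0%, 74.2% and 90.8%. Of unchanged rows, 0.21% and 0.26% were called in these comparisons. Other comparisons were less sensitive than mouse gRho against uninjected. Of 4-fold changes, 49.0% were called for human gRHO and 34.1% for saline against uninjected. Against saline these shares were 38.1% for mouse gRho and 21.4% for human gRHO. They were 57.1% between human and mouse gRho, and 58.2% for mouse gRho and 49.3% for human gRHO against WT. A list of 12 rows raised 2-fold was called in 10 of 10 simulations, and 0 of 190 unshifted lists were. The simulated miRNAs were independent of each other, unlike real ones.

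Alternatives fixed before the data were examined were DESeq2 1.42.0, median-of-ratios size factors, no TMM, no filter, a mean of at least 10 CPM, libraries as replicates, limma voom with the mouse as a random block, WT summed as 1 mouse, fits of only the groups compared, 1 series of title numbers, and leaving out each mouse. Added after seeing the data were all mature rows, leaving out 6 libraries with over 2% rRNA among aligned reads, the rRNA share as a covariate, leaving out 1 or both of the libraries poor in retinal miRNAs, leaving out the deep WT library for comparisons without WT, leaving out 13 rows set apart by 1 library and, for the lists, leaving out WT mouse 2 with both retina-poor libraries, leaving out the rRNA-rich libraries with the retina-poor mouse gRho library, fry in either direction, and an estimated correlation in each of these fits. The retina-poor libraries are the right eye of mouse gRho mouse 1 and uninjected mouse 2. They are the lowest of all libraries for the miR-183 and the miR-124 with miR-9 lists. A call on these lists that is lost without them thus cannot tell whether the difference belonged to the group.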

Results

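Small RNA libraries of 23 mouse retinas taken at postnatal day 90 were compared. Wild-type (WT) C57B retinas were set beside retinas of heterozygous P23H knock-in mice, a model of retinitis pigmentosa with a misfolding-prone rhodopsin. P23H mice were uninjected, given saline, or treated with DNA nanoparticles carrying the genomic form of human or mouse rhodopsin. Libraries held between 5968388 and 16048954 reads of mature miRNA. After the eyes of 1 mouse were summed, there were 2 WT, 3 uninjected, 1 saline, 2 human gRHO and 7 mouse gRho mice. Rows name a locus and no arm, so each value below is that of the deposited row.

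The comparison of uninjected P23H with WT retinas asked which miRNAs differ with the rhodopsin mutation. Of 382 rows, 3 were higher and 3 lower in P23H at an adjusted p of 0.05 (edgeR quasi-likelihood, n = 3 and 2 mice). The higher rows were mir-221, mir-23b and mir-193b. mir-221, of a family active in vascular cells, measured 32.0 ± 7.2 CPM (SD, n = 3) in uninjected P23H and 12.8 ± 6.8 (SD, n = 2) in WT, a log2 fold change of 1.33 (SE 0.31, adjusted p = 0.0378). mir-23b measured 16.8 ± 2.2 CPM against 6.3 ± 3.3, with a log2 fold change of 1.42 (SE 0.34, adjusted p = 0.0378). mir-193b, under 10 CPM, had a log2 fold change of 3.12 (SE 0.69, adjusted p = 0.0278).

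The lower rows were mir-381, of the imprinted Dlk1-Dio3 cluster, with mir-351 and mir-488. Their log2 fold changes were -4.58 (SE 0.88), -4.18 (SE 0.88) and -3.87 (SE 0.85), each with an adjusted p of 0.0278. These lower calls came from 1 WT library. mir-381 stood at 53.9 CPM in WT mouse 2 and at 2.26 CPM in WT mouse 1, against 1.13 ± 0.45 (SD, n = 3) in uninjected P23H. mir-351 stood at 37.2 and 1.08 CPM, and mir-488 at 23.8 and 1.29 CPM, in the same order. For mir-221, in contrast, WT mouse 1 at 17.6 CPM and WT mouse 2 at 7.99 CPM both lay below all 13 P23H mice, the lowest of which had 26.6 CPM. Leaving out WT mouse 2 or any 1 uninjected mouse left 0 calls, and leaving out WT mouse 1 gave 60. Without WT mouse 2 the log2 fold changes were 0.93 for mir-221, 1.04 for mir-23b and 2.25 for mir-193b, and -0.89 for mir-381, 0.035 for mir-351 and -0.57 for mir-488. No call remained without the 6 libraries rich in rRNA, without both libraries poor in retinal miRNAs, or with only these groups in the fit, and DESeq2 called 14. The 6 fold changes kept their direction in these fits. Without the rRNA-rich libraries, which leaves 1 uninjected mouse, mir-221 stood at 1.59 (SE 0.39), mir-23b at 1.55 (SE 0.41) and mir-381 at -4.39 (SE 1.52), with larger standard errors than above, and mir-221 stood at 1.40 and 1.37 in the other fits.

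**Figure D1:**
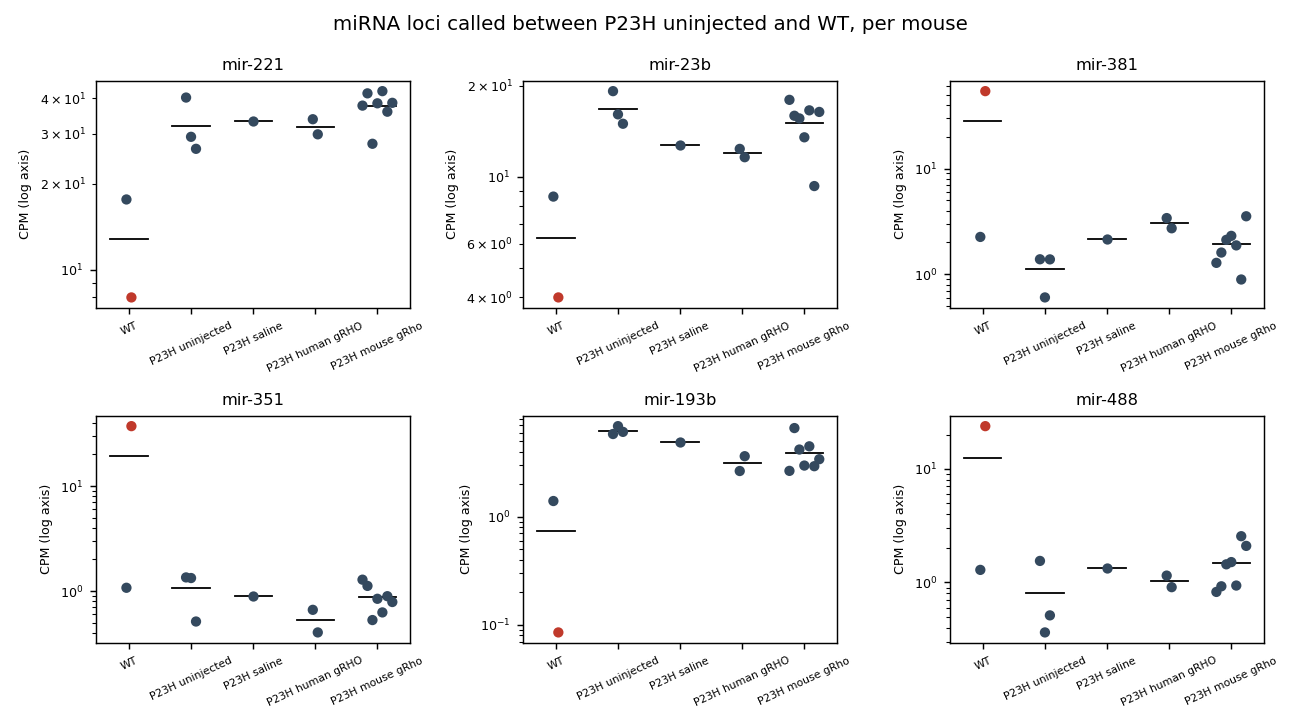
CPM per mouse (log axis) of the 6 rows called between uninjected P23H and WT. Each point is 1 mouse, the line is the group mean and WT mouse 2 is red: mir-381, mir-351 and mir-488 are high in that mouse alone, while mir-221 is lower in both WT mice than in all P23H mice.

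Rows of retinal miRNA loci were not among these calls. They name no arm, so it is not known whether each row counts the more abundant arm. The rows of mir-182, mir-96, mir-124-1 and mir-204 had medians of 1496, 737, 1030 and 1196 reads per library. A difference in them, or its absence, belongs to the deposited row, here and in the comparisons below. The miR-183 cluster, enriched in photoreceptors, had 3 of 3 rows lower in uninjected P23H and 0 past the threshold. mir-183 differed by -0.67 (log2, SE 0.53, adjusted p = 0.523), mir-182 by -1.02 (SE 0.53, adjusted p = 0.37) and mir-96 by -1.23 (SE 0.57, adjusted p = 0.299). The sign for mir-183 turned to 0.61 without WT mouse 1. The miR-124 and miR-9 rows, of miRNAs abundant in neurons, are locus copies that can share reads and are not separate measurements. Of these rows 6 of 6 were lower, by a median of -0.57, and 0 passed. The camera test gave adjusted p-values of 0.191 and 0.168 for these lists. The library of uninjected mouse 2 stood apart in both, at -2.11 and -1.52 (log2) from the median of 23 libraries, and the other 4 uninjected libraries lay between -0.877 and 0.256. Without both libraries poor in retinal miRNAs, the lowest of 23 for these lists, the list medians were -0.63 and -0.23 (camera adjusted p = 0.457 and 0.519). With WT mouse 1 as the only WT mouse they were -1.31 and -0.73 and both lists passed camera (adjusted p = 0.000662 and 0.000759; adjusted p = 0.512 with an estimated correlation for each). mir-204, of the pigment epithelium and Mueller glia, was 0.97 higher (log2, SE 0.31) and passed when adjusted over the list alone (adjusted p = 0.0117) but not over all rows (adjusted p = 0.146). mir-142a and mir-21a, of leukocytes and glial reactions, differed by -0.02 (SE 0.34) and -0.56 (SE 0.53). The mir-21a row held only 6 to 67 reads per library (median 22) and names no arm. Little can thus be read from it about glial reactions, here or in the comparisons below.

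Among the other lists, the Dlk1-Dio3 cluster passed the camera test, with 24 of 30 rows lower and a median log2 fold change of -0.30 (adjusted p = 0.0421; adjusted p = 0.821 with an estimated correlation). For this list too the library of uninjected mouse 2 lay lowest of the uninjected ones, at -0.90 beside -0.245 to -0.042, and without both libraries poor in retinal miRNAs the median was -0.14 and the list did not pass (adjusted p = 0.391). Only mir-381 of its members passed, over all rows and adjusted over the list alone. The median of that list was 0.05 with total reads as the scale, which moved the median of all rows by 0.43. Adjusted over the list alone, 2 of 10 Mueller glia rows passed (mir-204 and mir-99b), as did 1 of 4 endothelial and mural rows (mir-143, -1.43, SE 0.50). The Mueller glia list, with 6 rows higher and 4 lower, passed the fry test for changes in either direction (adjusted p = 0.0256), but not without WT mouse 2 (adjusted p = 0.755) or without the rRNA-rich libraries (adjusted p = 0.317). Camera adjusted p-values were 0.331 for the miR-181, activity-regulated and Mueller glia lists, 0.224 for surface epithelium with lens and cornea and 0.526 for the miR-204 family. They were 0.864 for miRNAs reported up in degeneration, 0.789 for microglia and leukocytes, 0.87 for endothelial and mural cells, 0.871 for red blood cells and 0.87 for muscle. The values were 0.789 for liver and let-7, 0.954 for miR-29 and 0.871 for miR-17/92. Some lists were tested only in part, mostly because two-level rows were set aside. Tested were 5 of 9 loci for degeneration, 6 of 8 for microglia and leukocytes, 5 of 9 for muscle and 1 of 4 for liver. The degeneration list thus lacked mir-146a, mir-155 and the mir-1a rows. For the miR-181, epithelium and miR-17/92 lists, 5 of 6, 7 of 9 and 11 of 14 loci were tested. In these lists 0 rows passed adjusted over the list alone, apart from those named. Median and mean differed in sign for the degeneration (-0.02 and 0.25), red blood cell (-0.06 and 0.01) and miR-17/92 (0.09 and -0.16) lists.

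**Figure D2:**
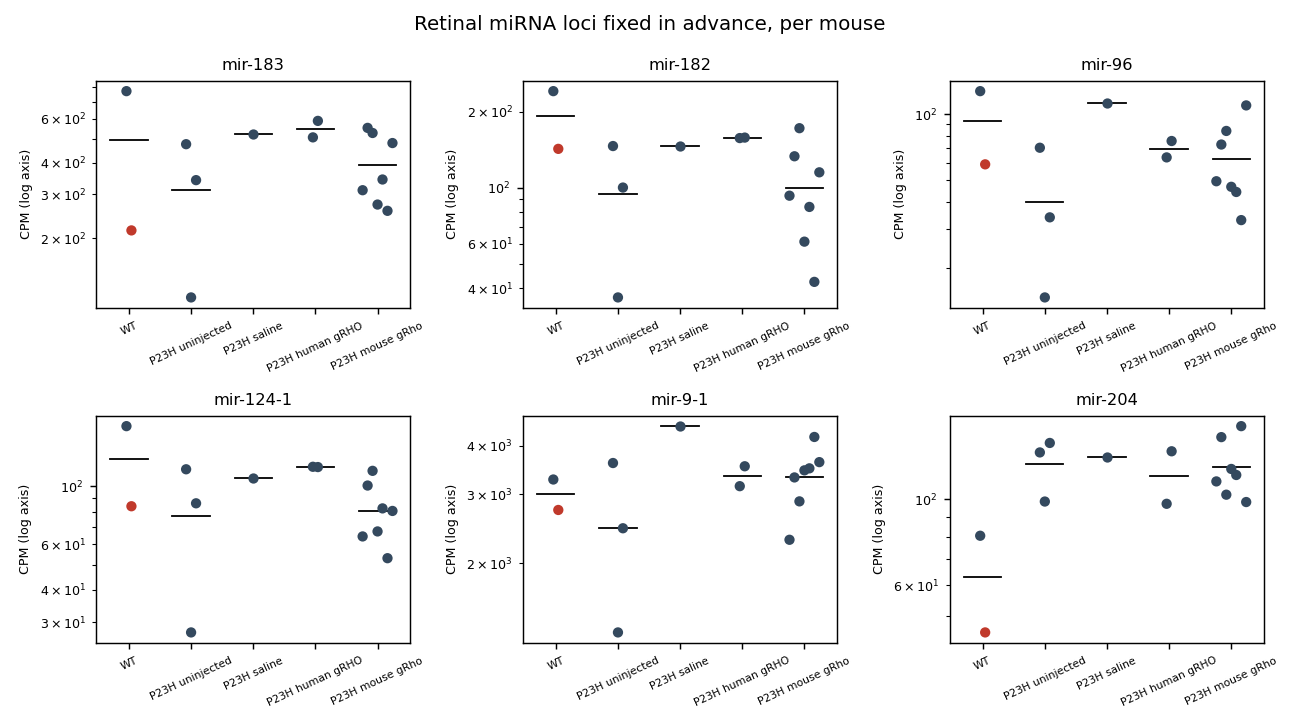
CPM per mouse (log axis) of 6 retinal rows chosen before the data were examined. Each point is 1 mouse, the line is the group mean and WT mouse 2 is red: the 3 uninjected mice spread from 116 to 475 CPM for mir-183, a range that lies below the saline mouse (523 CPM) and both human gRHO mice (506 and 588 CPM) and overlaps the WT and mouse gRho mice.

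Treatment with mouse gRho nanoparticles was compared with no injection (n = 7 and 3 mice) to ask whether it altered retinal miRNAs. No row passed (0 of 382 with edgeR and 0 with DESeq2), and 18 had an unadjusted p under 0.05 where 19.1 were expected by chance. The smallest p-values belonged to mir-296, mir-203b and mir-28a, with log2 fold changes of -0.83 (SE 0.23), -2.92 (SE 0.84) and -0.69 (SE 0.22) and an adjusted p of 0.533 each. mir-183, mir-182 and mir-96 differed by 0.33 (SE 0.42), 0.08 (SE 0.41) and 0.66 (SE 0.45). mir-124-1 differed by 0.07 (SE 0.35), mir-9-1 by 0.43 (SE 0.26), mir-204 by -0.03 (SE 0.23) and mir-211 by 0.20 (SE 0.25). mir-142a and mir-21a differed by -0.09 (SE 0.25) and 0.25 (SE 0.41). The Dlk1-Dio3 list had 26 of 30 rows higher, with a median of 0.35 (camera adjusted p = 0.000367; adjusted p = 0.941 with an estimated correlation). In this list the right eye of mouse gRho mouse 1 lay at -1.13 and uninjected mouse 2 at -0.90 from the median of 23 libraries, and without both libraries the median was 0.21 and the list did not pass (adjusted p = 0.0644).

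Human gRHO was compared with no injection (n = 2 and 3 mice). No row passed with edgeR or DESeq2, and 10 had an unadjusted p under 0.05. The smallest p-values were those of mir-5114 (log2 -1.36, SE 0.47), mir-7019 (-2.06, SE 0.73) and mir-28a (-0.80, SE 0.30), with an adjusted p of 0.93. The miR-183 cluster had 3 of 3 rows higher by a median of 0.80 and the miR-124 and miR-9 list 6 of 6 by 0.54. These lists and Dlk1-Dio3 (24 of 30 higher) passed camera, with adjusted p-values of 0.029, 0.00388 and 0.00388, and an adjusted p of 0.719 with an estimated correlation in each. None of them was called when both libraries poor in retinal miRNAs, uninjected mouse 2 among them, were left out (medians 0.38, 0.15 and 0.12, adjusted p = 0.421 each). These libraries were the lowest of all for the miR-183 and miR-124 with miR-9 lists. Their removal thus cannot tell whether the differences belonged to the groups. mir-204 differed by -0.10 (SE 0.30), mir-211 by 0.07 (SE 0.33), mir-142a by -0.39 (SE 0.34) and mir-21a by 0.08 (SE 0.54).

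Saline was compared with no injection as the control for the procedure (n = 1 and 3 mice). No row passed with edgeR or DESeq2, and 13 had an unadjusted p under 0.05. The smallest p-values were those of mir-7019 (-2.75, SE 1.03), mir-350 (-1.67, SE 0.64) and mir-1964 (-1.16, SE 0.47), with an adjusted p of 0.91. The miR-183 cluster and the miR-124 and miR-9 list were higher by medians of 0.75 and 0.72, and these lists and Dlk1-Dio3 passed camera (adjusted p = 0.0256, 0.000809 and 0.000809; adjusted p = 0.563 with an estimated correlation for each). With total reads as the scale the medians of the miR-183, miR-124 with miR-9 and Dlk1-Dio3 lists were 0.48, 0.45 and 0.20, since the median of all rows moved by -0.29. mir-96 was 2.84-fold as high (adjusted p = 0.91), mir-183 differed by 0.75 (SE 0.66) and mir-182 by 0.62 (SE 0.66). mir-204 differed by 0.06 (SE 0.38), mir-211 by 0.47 (SE 0.41), mir-142a by -0.45 (SE 0.44) and mir-21a by -0.75 (SE 0.71). Without both libraries poor in retinal miRNAs, uninjected mouse 2 among them, the medians of these lists were 0.34, 0.35 and 0.23 and 0 lists passed (adjusted p = 0.215, 0.119 and 0.119).

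The libraries differed in the levels of retinal miRNAs. The right eye of mouse gRho mouse 1 lay -4.24 (log2) from the median of 23 libraries for the miR-183 list and -3.44 for the miR-124 and miR-9 list. The left eye of the same mouse lay 0.43 above for each of these lists. The library of uninjected mouse 2 lay -2.11 and -1.52 from the median. The share of rRNA among aligned reads was 5.14% in uninjected mouse 2 and 3.41% over both eyes of uninjected mouse 3, against 0.36% in uninjected mouse 1 and 0.31% and 0.20% in the WT mice. Among mouse gRho libraries it was high too, at 6.20% in the left eye of mouse 2, 4.85% in mouse 6 and 3.08% in the right eye of mouse 3.

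**Figure D3:**
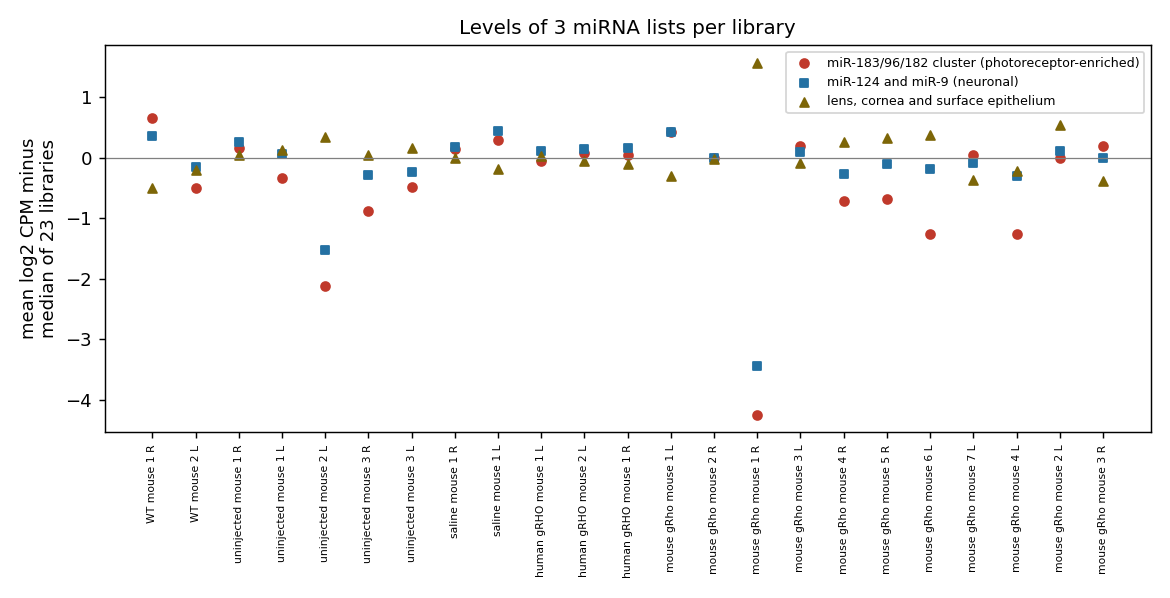
Mean log2 CPM of 3 miRNA lists in each of 23 libraries, as the difference from the median of all libraries. The right eye of mouse gRho mouse 1 lies lowest for the miR-183 (-4.24) and miR-124 with miR-9 (-3.44) lists and highest for the epithelium list (1.57).

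Treated retinas were set against saline. No row passed for mouse gRho (n = 7 and 1 mice), where 3 had an unadjusted p under 0.05, or for human gRHO (n = 2 and 1 mice), where 5 did; DESeq2 called 0 in both. The smallest p-values for mouse gRho belonged to mir-7019 (2.58, SE 0.99), mir-1964 (1.06, SE 0.44) and mir-5130, with an adjusted p of 0.995 each. mir-5130 had 0 reads in the saline mouse and 39 over the mouse gRho mice, and no fold is given. Those for human gRHO belonged to mir-7664 (1 read over the human gRHO mice and 14 in the saline mouse), mir-3062 (2.26, SE 0.94) and mir-7043 (7.97-fold lower), with an adjusted p of 0.996 each. The miR-124 and miR-9 list had 6 of 6 rows lower with mouse gRho than saline (median -0.44, camera adjusted p = 0.022; adjusted p = 0.718 with an estimated correlation). The right eye of mouse gRho mouse 1, at -3.44, belongs to this group, and without both libraries poor in retinal miRNAs the median was -0.30 and the list did not pass (adjusted p = 0.0676). Between human and mouse gRho (n = 2 and 7 mice), 0 rows passed with edgeR or DESeq2 and 11 had an unadjusted p under 0.05. The smallest p-values were those of mir-7019 (-1.89, SE 0.68), mir-7224 (-3.06, SE 1.16) and mir-7043 (-2.75, SE 1.05). With a median standard error of 0.51, this does not show that the constructs act alike.

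Treated retinas were also set against WT. With mouse gRho (n = 7 and 2 mice), 3 rows were higher and 9 lower. mir-221 measured 37.5 ± 4.9 CPM (SD, n = 7), a log2 fold change of 1.55 (SE 0.29, adjusted p = 0.00684). mir-23b and mir-193b differed by 1.26 (SE 0.31, adjusted p = 0.0316) and 2.44 (SE 0.64, adjusted p = 0.0422). The lower rows with a mean of at least 10 CPM over all mice were mir-335 (-1.71, SE 0.33, adjusted p = 0.00684) and mir-3535 (-0.77, SE 0.20, adjusted p = 0.0422). Those under that mean were the list members mir-381 (-3.86, SE 0.64) and mir-143 of smooth muscle and mural cells (-1.84, SE 0.41), with mir-351 (-4.44), mir-488 (-3.12), mir-193a (-2.96), mir-153 (-2.40) and mir-345 (-1.75), at adjusted p-values between 0.00201 and 0.0323. Without WT mouse 2 there were 0 calls, and the log2 fold changes were -0.17 for mir-381, -0.42 for mir-143, -0.73 for mir-335, -0.24 for mir-351, 0.21 for mir-488, 0.33 for mir-193a, -1.07 for mir-153 and -0.78 for mir-345, while mir-3535 stood at -0.87. Those of mir-221, mir-23b and mir-193b were 1.14, 0.86 and 1.53. Of the lists, 0 passed camera, and without WT mouse 2 there were 4, the miR-183, miR-124 with miR-9 and miR-17/92 lists lower and the epithelium list higher (adjusted p between 0.0238 and 0.0446; adjusted p between 0.54 and 0.763 with an estimated correlation). The right eye of mouse gRho mouse 1 was the lowest of 23 libraries for the miR-183 (-4.24) and miR-124 with miR-9 (-3.44) lists and the highest for the epithelium list (1.57), and with both libraries poor in retinal miRNAs left out as well 2 lists passed, miR-183 and miR-17/92 (adjusted p = 0.0334 each). Without WT mouse 1, 64 rows were called. Without the rRNA-rich libraries 7 rows were called, 6 of them among the 12, and with the rRNA share as a covariate 3 were called, 2 of them among the 12. With human gRHO (n = 2 and 2 mice), 0 rows passed with edgeR and 5 with DESeq2, and 38 had an unadjusted p under 0.05. The smallest p-values were those of mir-351 (-5.10, SE 1.10), mir-221 (1.32, SE 0.33) and mir-488 (-3.59, SE 0.98), with adjusted p-values of 0.108, 0.192 and 0.257. Without WT mouse 1, 46 rows were called.

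Whether treated retinas lay nearer to WT was asked with the covariance between treatment and genotype effects, both measured from the same uninjected mice. Across 382 rows, which are not independent, the covariance was 0.19 for mouse gRho, 0.23 for human gRHO and 0.23 for saline. Simulated groups without effects gave means of 0.18, 0.18 and 0.17, since the uninjected mice are shared. The differences were 0.01, 0.04 and 0.06, and 41.2%, 33.4% and 32.3% of 1000 simulations were as large as the observed values. The correlations were 0.40, 0.39 and 0.34, beside simulated means of 0.50, 0.38 and 0.27. Without uninjected mouse 1 the covariances were 0.371, 0.425 and 0.46, beside simulated means of 0.286, 0.285 and 0.286. Of 1000 simulations, 26.7%, 21.8% and 19.8% were as large. Without uninjected mouse 2 the covariances were 0.157, 0.159 and 0.171, below simulated means of 0.286, 0.284 and 0.285. As large were then 72%, 66.4% and 63% of 1000 simulations. Without uninjected mouse 3 the covariances were 0.251, 0.302 and 0.294, beside simulated means of 0.292, 0.29 and 0.293. With 1 uninjected mouse left out the covariances ranged from 0.157 to 0.371 for mouse gRho, from 0.159 to 0.425 for human gRHO and from 0.171 to 0.46 for saline. Treated mice and WT mouse 1 were not left out here. The 3 uninjected mice were too few to split with at least 2 in each part.

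Right and left eyes were compared within 8 mice. Of 330 rows, 0 passed with edgeR and 0 with limma voom, and 9 had an unadjusted p under 0.05 (smallest adjusted p = 0.952).

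Some rows were not compared because their counts jumped between levels. mir-146a, induced in inflammation, had 1 to 5 reads in 11 libraries and 2237 to 10641 in the other 12. mir-1a-2, a muscle miRNA, had 2 to 7 reads in 9 libraries and 59578 to 984970 in the other 14. Of 65 such rows, the eyes of 1 mouse lay at different levels in 31.0% on average, where 2 random libraries would in 32.7%.

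**Figure D4:**
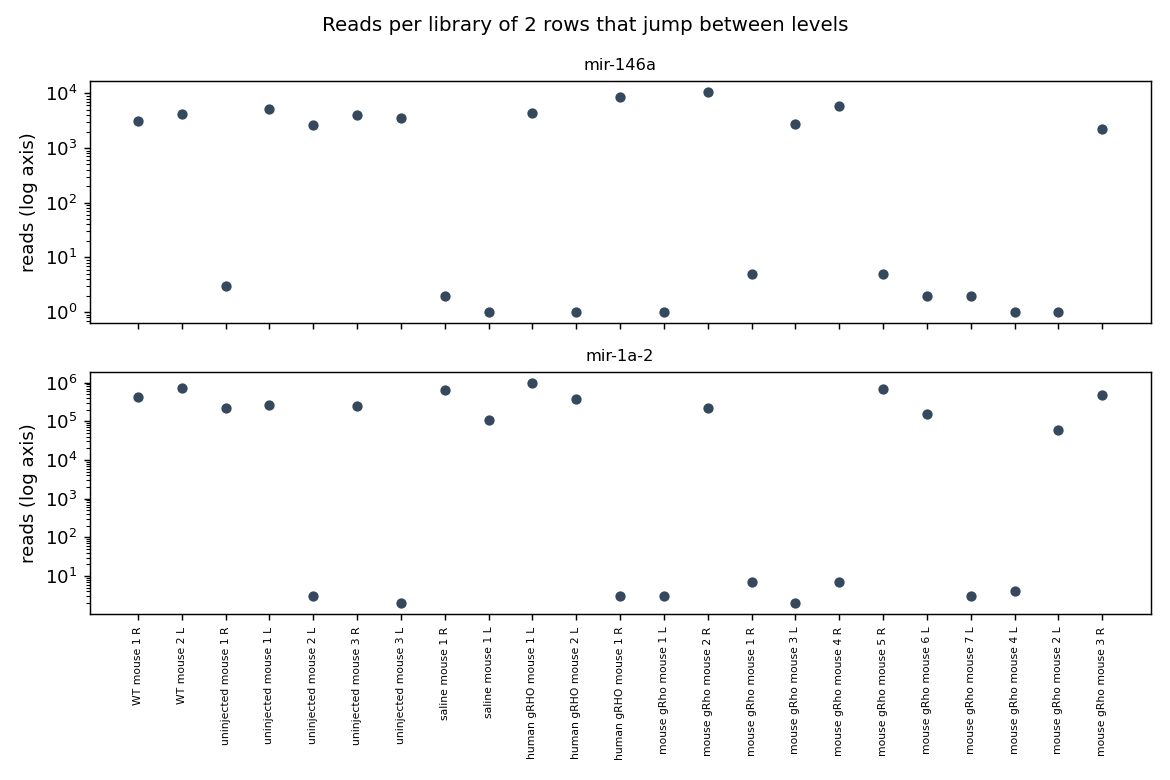
Reads per library (log axis) of mir-146a and mir-1a-2. Each point is 1 library, and both rows fall into separate levels, 1 to 5 against 2237 to 10641 reads for mir-146a.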

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

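The tests of the rows with 2 levels, of the rRNA-rich libraries, of the splits and of the fellow eye were chosen after the results were seen. The transfer between the WT mice and the count of each mouse alone were fixed before those values were computed, but after the calls without each WT mouse were known.

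In rows that jump between levels, the eyes of 1 mouse lay on different sides in 31.0% of cases, beside 32.7% for 2 random libraries. A level set by a state that both eyes share, such as genotype, would keep the eyes together. The ratio of 0.948 argues against it for these rows as a set, though in 10 of 65 rows no mouse was split between its eyes. A state that differs between the eyes, such as degeneration in 1 eye, was not tested by this. The levels lay a median of 22.2-fold apart, and the deepest library had 2.69 times the reads of the shallowest. This comparison cannot decide on depth. Counts were scaled to depth before the gap was taken, and the rule for these rows required a gap of at least 4-fold. A candidate explanation is that each library holds 1 of the 2 arms of a locus, taken without regard to the mouse. The files name no arm, so this stays a hypothesis. The highest such value was 984970 reads of mir-1a-2 in the left eye of human gRHO mouse 1, above the 728498 of the highest WT library.

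The calls against WT were 0 without WT mouse 2, and 60 and 64 without WT mouse 1. Set alone against the other 14 mice, WT mouse 2 gave 83 calls, and the next mouse, uninjected mouse 2, gave 11. Each of these tests has 1 mouse in an arm and takes its spread from the others, and the 83 in part restate the counts without each WT mouse. Of 64 rows called between WT mouse 2 and the mouse gRho mice, 36 kept their direction between WT mouse 1 and the uninjected mice, and the median ratio of log2 fold changes was 0.0363 (bootstrap interval -0.03 to 0.14 over rows). A genotype effect of like size in both WT mice would give a ratio above 0.5. The values argue against it for these rows as a set, though not for a single row such as mir-221. The rows were picked for large differences in WT mouse 2, which can lower the ratio. The interval over rows leaves out the spread between mice, and the P23H groups differ between the 2 fits. Whether genotype alters other rows was not tested by this. Whether rRNA-rich libraries among the uninjected mice contribute cannot be told apart from the group, because leaving them out leaves 1 uninjected mouse. The median ratio of log2 fold changes without over with these libraries was 0.952, while standard errors grew (mir-221 from 1.33, SE 0.31, to 1.59, SE 0.39).

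The right eye of mouse gRho mouse 1 was poor in retinal miRNAs. The fellow eye had a miR-183 level 0.43 above the median, which argues against a loss of photoreceptors in the mouse as a whole. Loss of photoreceptors in that eye alone stays open. The miR-183 cluster was at -4.96 (median log2 from the fellow eye) and the miR-124 and miR-9 rows at -3.75 with 6 of 6 lower. That median joins miR-124 rows at -5.1 to -5.72 and miR-9 rows at -2.16 to -2.39. The miR-181 rows of inner neurons were at -1.06 with a range of -1.54 to 0.28, and Mueller glia at 0.104. Tissue carried over at dissection is open as well. The muscle list differed by a median of 0.163, but only 5 of its 9 loci were tested. Of its two-level rows, mir-206 had 39434 reads in this eye and 14757 in the fellow eye. The other two-level rows had 87 and 22 reads (mir-1a-1) and 7 and 3 reads (mir-1a-2). The red blood cell list differed by 0.89, while the epithelium list was 1.91 and the endothelial list 1.43 higher.

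For mouse gRho against uninjected, the real grouping gave 0 calls and 18 rows at an unadjusted p under 0.05. Of 120 possible splits of these 10 mice into 7 and 3, 100 were drawn, the real one included. As many such rows came from 21 of them, with 43 in the highest other, so chance cannot be excluded for these rows. The highest count of calls in another split was 6.

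In 37 miRNAs named, the 7 mouse gRho mice were searched for a mouse far from the others, and 3 were found where chance gives 1.85. mir-142a stood at 56.5 CPM in mouse 5, beside a next value of 35.5. mir-203b stood at 0.656 CPM in mouse 7, beside 0.209. mir-7664 stood at 0.536 CPM in mouse 2, beside 0.262. In the rRNA counts of the alignment table, which entered only alternatives added later, rRNA took 6.20% of aligned reads in the left eye of mouse gRho mouse 2, above the 0.31% of the highest WT library.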

How the results depend on the processing

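Left out mice, DESeq2, scalings, filters and the fits of fewer groups were planned; the settings named as added were chosen after seeing the data. Of 389 refits of a miRNA called against WT, 267 kept direction and call, 119 lost the call and 3 changed sign. Of refits of miRNAs not called, 13 passed. The cause was not tested unless stated.

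Uninjected against WT (6 calls) gave 14 with DESeq2, 11 with no filter, 2 with limma voom (mir-193b and mir-221), and 0 with only these groups, 0 without the rRNA-rich libraries (added), 0 with the rRNA share as covariate (added), 0 without both retina-poor libraries (added), 0 without rows set apart by 1 library (added; this leaves mir-381, mir-351 and mir-488 untested, and the other 3 had an adjusted p of 0.0596 each), and 1 with all mature rows (added; mir-665). Leaving out 1 mouse gave 0 to 60. Mouse gRho against WT (12 calls) gave 7 without TMM, 5 at a mean of at least 10 CPM (fewer rows tested), 19 with each library as a replicate, 19 with limma voom, 7 without the rRNA-rich libraries (added) and 3 with the rRNA covariate (added); leaving out 1 mouse gave 0 to 64. Human gRHO against WT (0 calls) gave 5 with DESeq2, 4 with each library as a replicate, 4 with WT summed as 1 mouse, 1 with all mature rows (added; mir-665) and 1 with the rRNA covariate (added; mir-5126); leaving out 1 mouse gave 0 to 46. Mouse gRho against uninjected (0 calls) gave 1 with all mature rows (added; mir-224) and 0 to 1 when 1 mouse was left out (mir-3095 or mir-3078). Human gRHO against saline gave 2 with only these groups (mir-143 and mir-210) and 0 to 1 when 1 mouse was left out (mir-539), as did human against mouse gRho (0 to 1, mir-539). Right against left eye stayed at 0 in every setting run. These miRNAs were named after their values were seen. mir-665 and mir-224 are two-level rows, set aside in the main tests, so their calls cannot be read as differences between groups. mir-539 and mir-3078 had gaps of 1.80 and 1.76 (log2), close to the limit of 2 for such rows.

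Without WT mouse 2, mir-351 in uninjected against WT turned from -4.18 to 0.0355 (range over mice left out -5.05 to 0.0355). In mouse gRho against WT, mir-193a turned to 0.325 (range -3.80 to 0.325) and mir-488 to 0.213 (range -3.98 to 0.213). mir-183 in uninjected against WT turned to 0.609 without WT mouse 1 (range -1.27 to 0.609). With 1 uninjected mouse left out, the covariance ranged from 0.157 to 0.371 for mouse gRho, from 0.159 to 0.425 for human gRHO and from 0.171 to 0.46 for saline. The upper ends came without uninjected mouse 1 and the lower ends without uninjected mouse 2.

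Of the lists, 0 passed in any comparison with an estimated correlation or fry in 1 direction (fry in either direction, added: Mueller glia in uninjected against WT). Without the retina-poor libraries (added), which are the lowest for the miR-183 and miR-124 with miR-9 lists, 0 passed. Lists that passed camera went from 1 to 3 in uninjected against WT and from 0 to 4 in mouse gRho against WT without WT mouse 2, and these were 3 and 2 when the retina-poor libraries were left out as well (added). Mouse gRho against uninjected then had 2 (let-7 and Dlk1-Dio3), beside 1 with all mice. Without the rRNA-rich libraries (added), lists went from 1 to 4 in mouse gRho against saline, from 1 to 2 in mouse gRho against uninjected, from 1 to 0 in uninjected against WT, and from 3 to 0 and from 3 to 1 for human gRHO and saline against uninjected. With an estimated correlation, 0 of the lists passed in these fits (smallest adjusted p = 0.244). Without TMM, the median of all rows moved by 0.43, 0.25 and 0.23 in uninjected, mouse gRho and human gRHO against WT, by -0.29, -0.19 and -0.19 in saline, mouse gRho and human gRHO against uninjected, and by 0.10 and 0.11 in mouse gRho and human gRHO against saline. No paired analysis was possible because the groups compared hold different mice, no leading title number recurs across groups, and the replicate numbers used here only name the samples. If the leading title number is the cage, treatment cannot be told apart from cage. In the 257 rows with a mean under 10 CPM, a median of 17.2% of the fitted variance was counting error, beside 2.06% in the other 125. The rest was spread between the sums per mouse, which may be partly technical.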

Other observations

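The WT library of mouse 2 had the most mature miRNA reads (16048954) and the fewest miRNA species listed (527, beside 594 to 701 in the other libraries). It had 43 rows with 1 to 3 reads, beside 185 to 256 elsewhere. Of 24 rows in which 1 library stood alone beyond a gap of at least 4-fold, it was that library in 8 and the right eye of mouse gRho mouse 1 in 7. In this library mir-1a-1 had 729289 reads and mir-1a-2 had 728498, while mir-1a-1 had at most 98 reads in every other library.

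Rows of abundant families held very different counts. The row of let-7a-1 had 107566 to 493882 reads and that of let-7c-2 had 102862 to 465625, while let-7b had 61 to 246 and let-7c-1 had 44 to 195. Since let-7b is abundant in most tissues, a low count in its row is another value that does not tell which arm is counted.

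Without the 6 rRNA-rich libraries, an alternative chosen after seeing the data, the muscle and red blood cell lists were higher in mouse gRho than in the 1 remaining uninjected mouse (median log2 1.66 and 1.30, camera adjusted p = 0.00669 and 0.0167; adjusted p = 0.573 with an estimated correlation for each). The red blood cell list was also higher in the saline mouse than in that mouse (1.22), with 1 mouse on each side. From the median of 23 libraries, the eyes of the saline mouse lay at 0.795 and -0.543 for this list. Those of uninjected mouse 1 lay at -0.584 and -1.14. Against the saline mouse, mouse gRho had lower miR-183 and miR-124 with miR-9 lists (-0.41 and -0.43) and higher degeneration and endothelial with mural lists (0.96 and 0.62), with camera adjusted p-values between 0.000329 and 0.0422 and adjusted p-values between 0.326 and 0.589 with an estimated correlation. The right eye of mouse gRho mouse 1 stayed in this fit and lay at -4.24, -3.44, 0.88 and 1.10 for these lists, the direction of each. Without it as well, the miR-124 with miR-9 list alone passed against saline (-0.28, adjusted p = 0.0303; adjusted p = 0.859 with an estimated correlation), and against uninjected the muscle list passed (1.58, adjusted p = 0.00668; adjusted p = 0.74 with an estimated correlation) and the red blood cell list did not (adjusted p = 0.0737). These comparisons have 1 mouse in an arm, and saline against uninjected has 1 in each. Such a mouse is assumed to vary like the others, and no explanation was tested.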
